A study of Homo sapiens with 2 samples.

How the data were processed

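Gene expression was measured in human mesenchymal stromal cells (MSCs) from bone marrow, the adherent fibroblast-like cells of the marrow that can form fat, bone and cartilage. Per the labels' protocols, the cells grew in alpha-MEM with 20% serum, were infected with a lentivirus, and from 48 hours after infection were kept in 2 µg/ml puromycin for 72 hours. One virus carried a short hairpin RNA (shRNA) against CTGF and the other was the empty vector. From each culture, 200 ng of total RNA was amplified, labelled with biotin and hybridised to an Illumina HT-12 version 3 whole-genome bead array, on which each probe sits on a varying number of beads. Each sample was placed in its group by its label, which gave 1 CTGF shRNA array and 1 vector array. The labels used here name no donor, so it is not known here whether the cultures shared one.

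The deposited signal table holds 1 intensity per probe and array on a linear scale, summarised over the beads of the probe without background correction or normalization, per the file headers and name. It also holds a detection p-value per probe and array, which per the file headers comes with the signal; its steps correspond to a rank among 759 negative control probes. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The authors also deposited the mean intensity, its deviation and the bead number per probe, and the intensity and position of every bead. The authors' processed value table holds linear intensities of 34871 probes, with medians of 26.5 on the CTGF shRNA array and 26.6 on the vector array. How the authors corrected background and normalized that table is not given in the sources used here. Over 10016 probes detected on both arrays, the log2 ratios of the authors' table and of the values used here correlated with r = 0.987 across probes, so that table runs in the same direction.

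Background was removed from the 48803 probe intensities of each array with the normal-exponential model of limma 3.58.1 in R 4.3.3, with the background mean and SD estimated from the detection p-values because no control probes were named in the tables used here. The estimated background was 109 with an SD of 20.8 on the CTGF shRNA array and 104 with an SD of 18.5 on the vector array. An offset of 16 was added, the arrays were quantile normalized and log2 was taken. A probe was called detected at a detection p-value under 0.01. Of the probes of a gene, the one with the highest mean log2 value was used. Every log2 ratio is the CTGF shRNA array minus the vector array. A gene detected on 1 array only is described by a bound in place of a ratio. The bound sets the brighter value against the higher of the dimmer value and the lowest value of a detected probe on that array, which was 6.17 on the CTGF shRNA array and 6.18 on the vector array on the log2 scale.

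The platform annotation used here gave 1 gene symbol for 24570 probes and several for 6, and 24233 probes of the signal table had no single symbol. For 24537 probes the current symbol was taken through the gene ID, which kept or updated the listed one. Genes not named in the annotation used here were not analysed here. Genes of the Y chromosome, the pseudoautosomal regions, XIST and TSIX were left out of all tables. After this, 17138 genes remained. Probe and gene positions were not used here.

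With 1 array per group there is no replicate, so no test was run and no p-value is given. The number of arrays limits the precision. The error given with a log2 ratio is a bead standard error (SE), taken from the spread of a probe's beads within each array and carried through the normalization, and it covers measurement within an array only. The bead files carry numeric codes in place of probe names, so a code was paired with a probe where the rounded signals on both arrays matched 1 code only, which held for 11193 of 12229 detected probes (91.5%). The median number of beads per probe was 21 on each array.

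Before the data were examined, 26 gene lists, the alternatives and the rule for naming genes were fixed. The lists were the CCN family, adipocyte, osteoblast, chondrocyte, MSC surface and niche factors, extracellular matrix structure, matrix remodelling, TGF-beta targets, YAP and TAZ targets, smooth muscle and contractile, cell cycle G1/S and G2/M, p53 targets, interferon-stimulated, inflammatory cytokines, Wnt pathway, growth factors, integrins and focal adhesion, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid stress, oxidative stress and metallothionein, ribosomal proteins, and markers of haematopoietic, endothelial and epithelial cells. A list's median was taken over members detected on at least 1 array, with members detected on 1 array only at their normalized ratio, and set among the medians of 10000 random lists of the same size, matched on brightness in 20 bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5, as a description of these arrays. The median with such members at their bound was computed beside it. The genes named are CTGF and a fixed set of lead genes whatever their value (CCN1, PPARG, LEP, FABP4, LPL, RUNX2, ALPL, SPP1, SOX9, CXCL12, VCAM1, MKI67, CDKN1A, COL1A1, ACTA2 and IL6, with 1 further gene that is not reported here); the 12 highest and 12 lowest log2 ratios among genes detected on both arrays, at least 2-fold from equal and over 3 bead SE; the 5 largest bounds in each direction; and from each list up to 2 highest and 2 lowest members at least 1.5-fold from equal. Any other gene is said to have been chosen after its value was seen.

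The alternatives were no background correction, an offset of 50, scaling to a common median in place of quantile normalization, detection on both arrays, no detection filter, the mean of a gene's detected probes, the authors' processed values, and the median of bead intensities. The steps were tested on simulated data made from the vector array, with 200 genes changed by known folds. These were divided equally among 2-fold and 3-fold changes in each direction, and percentages are over those still detected on both simulated arrays. Of those made 2-fold higher 50 were, and 98.0% came out at least 1.5-fold higher. Of those made 2-fold lower 46 were, and 100% came out at least 1.5-fold lower. For 3-fold changes 49 higher and 36 lower genes were, and 100% came out at least 1.5-fold from equal in the right direction. Genes lost to detection are not in these percentages, and more were lost among those made lower. Of 7367 unchanged genes measured on both, 0 came out at least 2-fold from equal and 38 at least 1.5-fold. Both simulated arrays were made from the vector array with bead noise as the only noise. The simulation therefore holds no spread between cultures or hybridisations and gives no error rate for the real comparison. A simulated list of 30 shifted genes reached percentile 100, and 4 of 200 unshifted lists fell outside the central 95%. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.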

Results

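The series asks which genes depend on connective tissue growth factor (CTGF, also named CCN2), a secreted matrix-associated protein, in human MSCs from bone marrow. Cells carrying a CTGF shRNA were compared with cells carrying the empty lentiviral vector, on 1 array each. Each array held 48803 probes, of which 11653 were detected on the CTGF shRNA array and 11639 on the vector array. Median raw signals were 117 and 112, close to the estimated background of 109 and 104. Of the 17138 named genes, 8133 were detected on at least 1 array and 7499 on both. There were no replicates, so no difference below was tested against the spread between cultures. Errors are bead SEs, which cover measurement within an array only, and higher or lower describes this pair of arrays.

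The targeted gene was measured by 1 probe (ILMN_2115125). Its raw signal was 13881 on the CTGF shRNA array and 20954 on the vector array. After normalization the log2 ratio was -0.64 ± 0.11, a level 1.56-fold lower (-35.8%) on the CTGF shRNA array. The direction is the one the labels give. CTGF ranked 441 from the lowest of the 7499 genes detected on both arrays, so many genes differed by more than the target did. No gene at least as bright as CTGF on the vector array lay further from equal, among 54 such genes. Of the CCN family, to which CTGF belongs, 4 other members were named on the array and 1 was detected, CCN1 (CYR61), with a log2 ratio of 0.22 ± 0.09. With 1 detected member, that list was given no percentile.

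Among genes detected on both arrays, 74 were at least 2-fold higher and 102 at least 2-fold lower on the CTGF shRNA array, and 515 and 533 passed 1.5-fold. COL15A1, a collagen of basement membrane zones, had the highest ratio, 6.98-fold higher with a log2 ratio of 2.80 ± 0.12. It was followed by MT1M, a metallothionein (2.19 ± 0.20), PALM, a membrane-associated phosphoprotein (2.07 ± 0.17), and PPP1R14A, an inhibitor of myosin phosphatase (1.89 ± 0.23). KISS1, which encodes the kisspeptin precursor, had a log2 ratio of 1.62 ± 0.31. TPD52L1 (1.52 ± 0.11), the carboxypeptidase CPA4 (1.5 ± 0.17), the heparan sulfate proteoglycan GPC1 (1.47 ± 0.12) and the junction protein JUP (1.46 ± 0.14) came next. ABTB1 (1.46 ± 0.26), the laminin chain LAMA5 (1.43 ± 0.28) and GRIPAP1 (1.41 ± 0.29) completed the 12 highest. Without background correction, which pulls ratios of dim probes toward equal, the order differed. PALM then had a log2 ratio of 1.29, below PPP1R14A (1.48), CPA4 (1.43) and GPC1 (1.30), and ABTB1 (0.89), LAMA5 (0.87) and GRIPAP1 (0.90) were less than 2-fold higher. MT1M belongs to a family of near-identical copies, and its probe may not tell them apart.

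The lowest ratio was that of COLEC12, a scavenger receptor of the collectin family, 3.64-fold lower with a log2 ratio of -1.86 ± 0.15. SCML1 (-1.77 ± 0.20), the secreted proteoglycan ESM1 (-1.74 ± 0.11) and the lipid phosphatase PLPP3 (-1.70 ± 0.17) followed. The mitotic kinase NEK7 had a log2 ratio of -1.59 ± 0.22 and the secreted glycoprotein STC1 one of -1.56 ± 0.09. ANXA10 (-1.55 ± 0.23), the microtubule-binding protein MAP1B (-1.51 ± 0.20) and the Cdc42 effector CDC42EP3 (-1.51 ± 0.24) were also among the 12 lowest. So were TRAM1, a component of protein translocation into the endoplasmic reticulum (-1.49 ± 0.09), and the phosphodiesterase PDE7B (-1.49 ± 0.12). SKP2, the ubiquitin ligase subunit that targets the cell cycle inhibitor CDKN1B, had a log2 ratio of -1.47 ± 0.15 at its brighter probe and 0.10 at its other probe. With the mean of both probes the ratio of SKP2 was -0.68. Its other probe was dim, at 6.37 on the CTGF shRNA array and 6.27 on the vector array on the log2 scale. The lowest values of detected probes were 6.17 and 6.18. Without background correction SCML1 had a log2 ratio of -1.06, nearer to 0 than ESM1 (-1.47), PLPP3 (-1.57), STC1 (-1.34) and TRAM1 (-1.47), and ANXA10 (-0.98), MAP1B (-0.95) and CDC42EP3 (-0.92) were less than 2-fold lower.

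Genes detected on 1 array only are given by a bound, brighter over dimmer, since the other array was not well above background. A fold given as at least, here and below, is this bound without its bead noise, so the difference can be smaller. For the genes named in this paragraph, the bead SE of the normalized log2 ratio ran from 0.21 (RNF13) to 0.38 (OSMR). By that bound 20 genes were at least 2-fold higher and 8 at least 2-fold lower on the CTGF shRNA array. The largest bounds were MT1F, at least 4.94-fold higher, the chemokine receptor ACKR3, at least 4.26-fold, the sialyltransferase ST6GAL1, at least 2.97-fold, DENND2A, at least 2.96-fold, and EFHD1, at least 2.81-fold. In the other direction were OSMR, the oncostatin M receptor, at least 2.98-fold lower, HNRNPA3, at least 2.57-fold, HNRNPA1, at least 2.42-fold, ECE2, at least 2.39-fold, and RNF13, at least 2.28-fold. MT1F, HNRNPA3 and HNRNPA1 have near-identical copies in the genome and are uncertain for that reason.

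All 176 genes past 2-fold exceeded 3 bead SE, and bead noise alone would put 1.14 genes there. Of 26 probe pairs of one gene whose brighter probe was past 2-fold, the other probe had the same sign in 24 and was also at least 1.5-fold from equal in 19. Over all 1301 pairs, 69.4% had the same sign, with r = 0.625 across pairs. These pairs gave an SD of 0.25 for the log2 ratio of 1 probe, against a median bead SE of 0.14. Bead SE therefore covers only part of the spread between probes of one gene. With the authors' processed values 115 genes were at least 2-fold higher and 104 lower, so higher genes made up 52.5% of these against 42.0% in the main values. With median scaling in place of quantile normalization the counts were 61 and 115 (34.7% higher), and 443 and 625 genes passed 1.5-fold. Without background correction the 2-fold counts were 19 and 40.

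**Figure D1:**
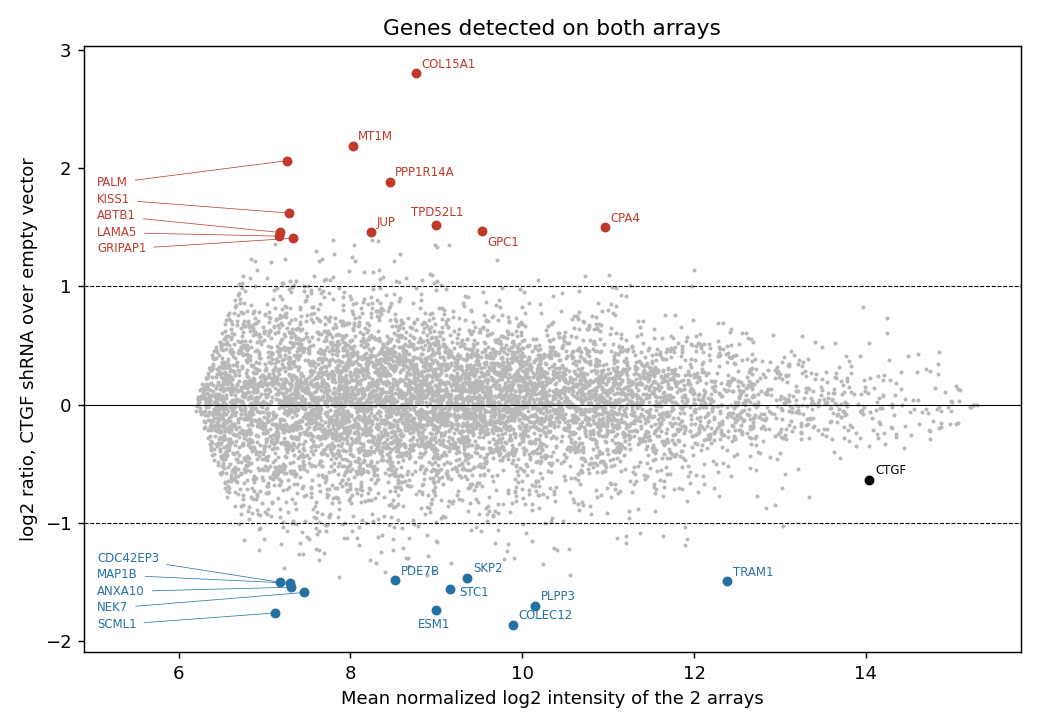
Log2 ratio (CTGF shRNA over empty vector) against the mean normalized log2 intensity for the 7499 genes detected on both arrays, with dashed lines at 2-fold, red for the 12 highest genes, blue for the 12 lowest and black for CTGF. COL15A1 stands highest at 2.80 and COLEC12 lowest at -1.86, while CTGF lies at -0.64 among the brightest genes.

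List medians below are over all members detected on at least 1 array, those detected on 1 array entering at their normalized ratio, while counts above and below 0 are over members detected on both. The median with those detected on 1 array at their bound, or over members detected on both arrays, is added for some of the lists where it differs. Genes of the cell division cycle were lower together on the CTGF shRNA array. In the G2/M list, which holds genes of mitosis, 35 members were detected on both arrays. All 35 had a log2 ratio below 0, 27 of them at least 1.5-fold lower, and 0 were at least 1.5-fold higher. The median log2 ratio over 38 detected members was -0.81 (-43.1%), at percentile 0 of random lists matched on brightness, whose central 95% ran from -0.12 to 0.18. The spindle checkpoint kinase TTK (-1.27 ± 0.19) and the hyaluronan receptor HMMR (-1.12 ± 0.18) were the lowest of the members detected on both arrays. Named after their values were seen, the mitotic kinase CDK1 (-0.99 ± 0.21), cyclin A2 (CCNA2, -1.01 ± 0.13) and topoisomerase TOP2A (-0.71 ± 0.10) lay between these and NEK2 (-0.14 ± 0.27), the member nearest to 0. The proliferation marker MKI67 was detected on the vector array only and was at least 1.47-fold lower on the CTGF shRNA array.

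In the G1/S list, which holds genes of DNA replication, 21 of 23 members detected on both arrays lay below 0 and 7 were at least 1.5-fold lower. The median over 25 detected members was -0.43 (-26.0%), at percentile 0. The ribonucleotide reductase subunit RRM2 (-0.99 ± 0.16) and the replication clamp PCNA (-0.96 ± 0.26) were the lowest. The members above 0 were MCM6 (0.07 ± 0.10) and CCNE1 (0.54 ± 0.14), named after their values were seen. Of the list of p53 targets and cell cycle inhibitors, 10 members lay above 0 and 7 below, and the median over 18 detected members was 0.14 at percentile 85.7, which did not stand apart. In it SESN2 (0.63 ± 0.24) passed 1.5-fold, and TP53INP1, a p53-induced gene, was at least 2.56-fold higher. CDKN1A, the best-known p53 target of this list, was not detected on either array.

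**Figure D2:**
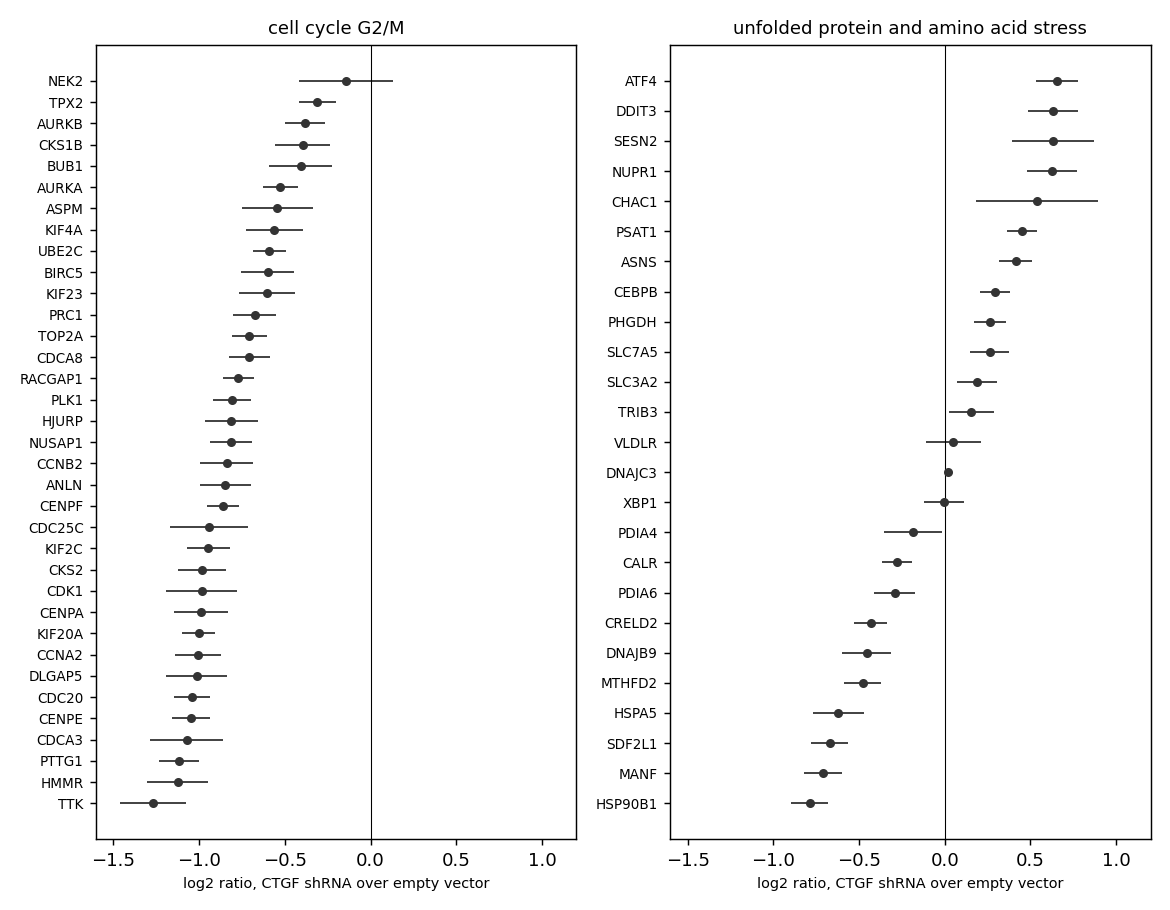
Log2 ratio (CTGF shRNA over empty vector) of each member detected on both arrays of the G2/M list (left) and of the unfolded protein and amino acid stress list (right), with bars of 1 bead SE, which DNAJC3 lacks. All 35 G2/M members lie below 0, while the stress list divides into 14 above and 11 below 0.

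Genes of glycolysis and of the response to low oxygen were also lower. Of 26 members detected on both arrays, 24 lay below 0 and 4 were at least 1.5-fold lower, with a median of -0.32 (-19.7%) at percentile 0. The aldolase ALDOC (-0.98 ± 0.11) and the carbonic anhydrase CA12 (-0.90 ± 0.11) were the lowest. The glucose transporter SLC2A1 (-0.60 ± 0.09) and the glycolytic enzyme PGAM1 (-0.70 ± 0.11), named after their values were seen, were the others past 1.5-fold. Above 0 were PKM (0.04 ± 0.10) and HK1 (0.23 ± 0.06), also named after their values were seen. Ribosomal protein genes showed a small difference across nearly the whole list. Of 41 members, 37 lay below 0 with a median of -0.20 (-12.9%), at percentile 0. RPL5 (-1.30 ± 0.22) and RPL29 (-1.18 ± 0.09, with -0.95 at its other probe) were the members past 1.5-fold. Ribosomal protein probes can bind RNA of many processed pseudogenes, so single members are uncertain.

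Inflammatory cytokine genes were lower and interferon-stimulated genes higher. In the inflammatory list 10 of 13 members detected on both arrays lay below 0. The median over all 15 detected members was -0.35 (-21.4%) at percentile 0.28, or -0.30 with bounds, and over the 13 it was -0.32 at percentile 0.57. PTGES, which makes prostaglandin E (-0.96 ± 0.22), and TNFAIP3, an inhibitor of NF-kappaB signalling (-0.82 ± 0.13), were at least 1.5-fold lower. The cytokine IL6 had a log2 ratio of -0.30 ± 0.10. The adhesion molecule VCAM1 went the other way, with 0.71 ± 0.15 at its brighter probe, -0.32 at its other probe and 0.19 as the mean of both. That other probe was dim, at 6.26 on the CTGF shRNA array and 6.58 on the vector array on the log2 scale. The lowest values of detected probes were 6.17 and 6.18. Without a detection filter the inflammatory median was -0.091, at percentile 4.03, and no longer stood apart. For 12 members detected on both arrays, medians of beads gave -0.41 from all beads, and -0.42 and -0.14 from those in separate parts of the strip. The difference was thus smaller in the latter part, and a local artefact was not tested for this list.

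In the interferon-stimulated list 10 of 15 members detected on both arrays lay above 0, with a median of 0.35 at percentile 99.5. Over all 18 detected members the median was 0.40 (31.8%) at percentile 99.7, also with bounds. MX1, an antiviral GTPase, had a log2 ratio of 0.65 ± 0.21, and IFI27 was detected on the CTGF shRNA array only, at least 2.10-fold higher. The normalized log2 ratio of IFI27 was 1.07 ± 0.36. ISG20, an exonuclease, had a log2 ratio of -0.70 ± 0.22. The other members below 0, named after their values were seen, were IFI6 (-0.41 ± 0.19), EIF2AK2 (-0.37 ± 0.16), ISG15 (-0.35 ± 0.39) and IFI44 (-0.06 ± 0.15). Of the 15 members detected on both arrays, 13 lay within 1.5-fold of equal. For the 15 members detected on both arrays, medians of beads gave 0.30 from all beads of each array, and 0.22 and 0.25 from those in separate parts of the strip.

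The lists of the lineages that MSCs can form did not stand apart. Of adipocyte genes detected on both arrays, 11 lay above 0 and 4 below, with a median of 0.12 at percentile 83.4. Over all 16 detected members, PDK4 included, the median was 0.18 at percentile 93.4. Among members detected on both arrays, the lipid carrier APOE (0.97 ± 0.12) was the highest and the fatty acid binding protein FABP5 (-0.74 ± 0.08) the lowest. PDK4, a kinase that restrains glucose oxidation, was at least 2.68-fold higher. PPARG, the nuclear receptor that drives fat cell formation, had a log2 ratio of 0.48 ± 0.23, about 2 bead SE from equal. The fat cell products LEP, FABP4 and LPL were not detected on either array. PNPLA2 (0.72 ± 0.15), named after its value was seen, also passed 1.5-fold.

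Osteoblast genes were divided, with 5 above and 5 below 0 and a median of -0.01 at percentile 38.3. ALPL, the alkaline phosphatase of bone-forming cells, was 2.02-fold higher (1.02 ± 0.10) and the transcription factor ATF4 1.58-fold higher (0.66 ± 0.12). The gap junction protein GJA1 (-1.10 ± 0.24) and TNFRSF11B, the decoy receptor osteoprotegerin (-0.74 ± 0.11), were lower. Osteopontin (SPP1) had a log2 ratio of -0.36 ± 0.22 and COL1A1 one of 0.45 ± 0.10, and RUNX2 was not detected on either array. Chondrocyte genes had a median of 0.30 at percentile 92.9, or 0.22 with bounds, over 8 detected members. Of these GDF5 (0.78 ± 0.18) passed 1.5-fold, SOX9, the cartilage transcription factor, had a log2 ratio of 0.34 ± 0.17, and COL10A1 was at least 1.78-fold lower. Without a detection filter the chondrocyte median was 0.21 and stood apart at percentile 99.1. Adipocyte genes did so with bead medians, at 0.28 and percentile 99.1.

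Niche and surface factors of MSCs differed in both directions, with 9 of 19 members detected on both arrays above 0 and 10 below. CXCL12, the chemokine that holds blood stem cells in the marrow, was 2.0-fold higher (1.0 ± 0.14), with 1.08 and 0.30 at its other probes. ANGPT1, a ligand of the TEK receptor (-1.25 ± 0.17), and BST1 (-1.07 ± 0.16) were lower, as were the growth factor FGF2 (-0.97 ± 0.17) and the nucleotidase NT5E (-0.73 ± 0.23). The list's median over 20 detected members was -0.11 at percentile 6.73, and with the mean of each gene's probes it was -0.17 at percentile 1.58, which stood apart.

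Structural genes of the extracellular matrix were divided. Of 34 members detected on both arrays, 16 lay above and 18 below 0, with a median of -0.04 at percentile 16.04. Over all 36 detected members the median was 0.01 at percentile 43.9, or -0.0004 with bounds, so its sign depends on the genes detected on 1 array. FBLN2 (0.82 ± 0.16) and lumican (LUM, 0.59 ± 0.12) were the highest, and the laminin chain LAMA4 (-0.91 ± 0.12) and COL12A1 (-0.76 ± 0.13) the lowest. Among matrix remodelling genes 12 lay above and 14 below 0, and the median over 29 detected members was -0.05 at percentile 17.5, against -0.03 over those detected on both arrays. All 4 members past 1.5-fold were lower. They were the crosslinking enzyme LOXL1 (-1.35 ± 0.11, with -1.54 at its other probe), the plasminogen activator PLAT (-1.03 ± 0.10) and, named after their values were seen, PLAUR (-0.88 ± 0.14) and LOXL3 (-0.84 ± 0.10). That list stood apart with the mean of probes, at -0.15 and percentile 1.56, and with bead medians, at -0.16 and percentile 1.42.

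TGF-beta targets had a median of -0.07 at percentile 15.2 over 20 detected members, and 8 of those detected on both arrays lay above and 11 below 0. The transcriptional inhibitors ID2 (-0.64 ± 0.22) and ID3 (-0.60 ± 0.11) were the members past 1.5-fold. Targets of the mechanosensitive regulators YAP and TAZ had a median of -0.05 at percentile 20.9 over 21 detected members, or -0.03 with bounds. In that list ARHGEF17 (0.68 ± 0.12) and WWC1 (0.67 ± 0.22) were the highest, and PTPN14 (-1.23 ± 0.17) and NT5E the lowest. Contractile genes had a median of 0.09 at percentile 82.4, with CNN1 at 0.68 ± 0.12, PDLIM5 at -0.61 ± 0.20, ACTA2 at -0.25 ± 0.12 and ACTG2 at least 1.59-fold lower. Integrin and focal adhesion genes had a median of 0.09 at percentile 81.8, with 15 above and 7 below 0, and TLN2 (-0.60 ± 0.17) was the member past 1.5-fold.

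Wnt pathway genes had a median of -0.02 at percentile 32.9 over 19 detected members and of -0.08 at percentile 17.5 over those detected on both arrays. The receptor FZD2 was higher (0.74 ± 0.09) and the secreted inhibitor SFRP4 at least 1.62-fold higher, while the secreted inhibitors SFRP1 (-0.73 ± 0.18) and DKK1 (-0.71 ± 0.14) were lower. CTNNB1, named after its value was seen, also passed 1.5-fold (-0.66 ± 0.12). Growth factors and their binding proteins had a median of -0.07 at percentile 15.5 over 21 detected members and of -0.09 over those detected on both arrays. The IGF-binding proteins IGFBP4 (0.83 ± 0.09) and IGFBP2 (0.78 ± 0.11) were the highest, and STC1 and FGF2 the lowest.

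The stress list held opposite differences, with 14 members above and 11 below 0 and a median of 0.05 at percentile 62.9. The chaperone HSP90B1 (-0.79 ± 0.11) and MANF (-0.71 ± 0.11), both residents of the endoplasmic reticulum, were lower. Their neighbours SDF2L1 (-0.67 ± 0.11) and HSPA5 (-0.62 ± 0.15), named after their values were seen, were the other members at least 1.5-fold lower. ATF4 and DDIT3 (0.63 ± 0.15), transcription factors of the amino acid and stress response, were higher. SESN2 and NUPR1 (0.62 ± 0.15), the latter named after its value was seen, were the other members at least 1.5-fold higher.

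Oxidative stress and metallothionein genes had a median of 0.16 at percentile 92.7, where MT1M was the measured member past 1.5-fold. With bead medians that list stood apart, at 0.24 and percentile 98.9. Cholesterol synthesis genes had a median of 0.19 at percentile 90.8 over 15 detected members and of 0.16 over those detected on both arrays, with EBP at -0.59 ± 0.15 and TM7SF2 at least 1.53-fold higher.

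Markers of other cell types were mostly not detected. Of 19 haematopoietic markers named on the array 5 were detected, with a median of -0.17 at percentile 21.3, or -0.21 over the 4 detected on both arrays. The monocyte marker CD14 had a log2 ratio of 0.92 ± 0.26 and the receptor CSF1R one of -1.0 ± 0.16, in opposite directions. Of 16 endothelial markers 2 were detected, with a median of -0.32 at percentile 19.4, or -0.07 with bounds, and of 14 epithelial markers 4 were detected, with a median of -0.01 at percentile 42.9.

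In all, 6 of the 25 lists with a percentile stood apart, 1 higher and 5 lower, where 1.25 would by chance if lists were independent and genes within a list unrelated. The median and the mean differed in sign for the osteoblast list (-0.01 and 0.01) and the epithelial list (-0.01 and 0.09), both near 0. No list that stood apart differed in sign between its median, its mean and its median with bounds.

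**Figure D3:**
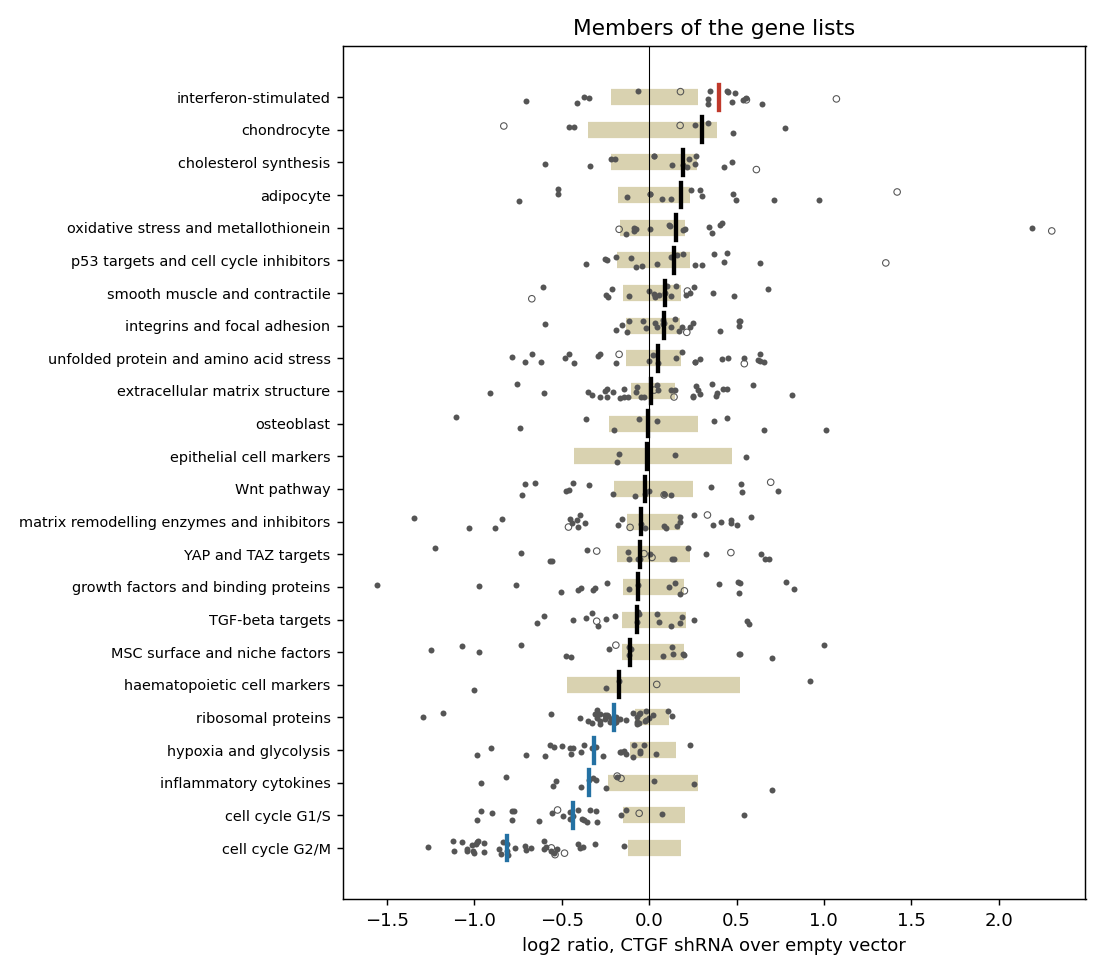
Log2 ratio (CTGF shRNA over empty vector) of the members of each list with at least 3 detected genes, with filled points for members detected on both arrays, open points at the bound of those detected on 1, a thick line at the list's median (with the latter at their normalized ratio) and a tan bar over the central 95% of medians of random lists. The 5 blue medians, from -0.81 for G2/M to -0.20 for ribosomal proteins, and the red median of 0.40 for interferon-stimulated genes lie outside their bars.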

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

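The tests of the quantile normalization, the number of arrays, control shRNA arrays and saturation of the CTGF probe were chosen only after the results were seen. Probes without a gene name in the annotation used here entered no comparison of the report. Of 2052 such probes detected on both arrays, 53 were at least 2-fold from equal (2.58%, exact 95% interval 1.94% to 3.37%), 23 higher and 30 lower, against 2.55% of 8994 named probes.

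All 35 genes of the G2/M list measured on both arrays were lower on the CTGF shRNA array. A local artefact confined to either part of the strip is argued against. The list's median was -0.84 in the part with the smaller difference, where bead noise has an SD of 0.04. The strip was divided only at the median bead position on a single axis. An artefact reaching across both parts would not be seen this way. The quantile normalization is argued against too, since with median scaling in its place, which moved CTGF from -0.64 to -0.80, the list's median was -0.84. A difference between single cultures unrelated to CTGF, such as confluence or the course of selection, cannot be told apart from an effect of the shRNA with 1 array per group. Nor can a response to any shRNA be told apart from one to the loss of CTGF, since the control was an empty vector. The same holds for every difference in this report. A lower share of dividing cells after loss of CTGF is therefore an untested hypothesis.

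Interferon-stimulated genes were higher, with a median log2 ratio of 0.40 over all 18 detected members. Bead noise of dim probes is argued against, since the median was 7.02 times the SD that bead noise alone gives. That median includes members detected on 1 array only, and the SD leaves out other spread between probes of one gene. Over the 15 members detected on both arrays the median was 0.35. A local artefact confined to a part of the strip was not decided by the mark set in advance. For the 15 members detected on both arrays, the medians were 0.22 and 0.25 in the separate parts. From all beads treated alike the median was 0.30. The 0.22 was too close to the mark of 0.2, beside a bead noise SD of 0.08. That SD was taken from errors of bead means, while these values are bead medians. Over 7103 genes, log2 ratios of the separate parts correlated with r = 0.587 across genes. Read after the values were seen, both medians lay above 0, so they do not place the difference in a single part. A response to any shRNA cannot be told apart from one to the loss of CTGF, since the control was an empty vector and 0 arrays of a control shRNA were analysed here.

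CTGF itself differed less than many other genes, with a log2 ratio of -0.64. Saturated beads are argued against, since its signal on the vector array was 53.1% of the highest probe signal. A local artefact confined to either part of the strip is argued against as well, with -0.74 and -0.75 from the separate parts. All values from parts of the strip are bead medians shifted so that the median gene lies at 0, a measure unlike the -0.64. Compression of ratios at bright probes may contribute, since 0 of 54 genes at least as bright lay further from equal, although 6 of 195 genes within 2-fold of its brightness did. Brightness was taken on the vector array only. IGFBP4, among the 6, reached 14.38 on the CTGF shRNA array on the log2 scale, against 14.36 for CTGF on the vector array. Its log2 ratio was 0.83. If ratios are compressed, the residual CTGF level of the cultures could be lower than the array shows, which these data do not settle.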

How the results depend on the processing

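Of the alternatives, all planned, none reversed a named gene at least 1.5-fold from equal or a list that stood apart, while medians of some lists that did not stand apart crossed 0. The lists that stood apart did so under all 8 alternatives, except inflammatory cytokines, with medians from -0.85 to -0.67 for G2/M, -0.49 to -0.38 for G1/S, -0.38 to -0.30 for hypoxia and glycolysis, -0.32 to -0.18 for ribosomal proteins and 0.25 to 0.45 for interferon-stimulated genes. CTGF ranged from -0.63 to -0.80, the latter with median scaling (-42.7%). Without background correction, which pulls ratios of dim probes toward equal, 19 genes were at least 2-fold higher and 40 lower, 246 and 299 passed 1.5-fold, and the SD of the difference between probes of one gene was 0.28 in place of 0.35. With an offset of 50 the 2-fold counts were 39 and 65 and that SD 0.32. Without a detection filter, which lets more genes in, 154 genes were at least 2-fold higher and 152 lower (50.3% higher against 42.0%), and 845 and 792 passed 1.5-fold. There the chondrocyte median was 0.21 (percentile 99.1) and the inflammatory median -0.091 (percentile 4.03). With the mean of a gene's probes, the MSC surface and niche median was -0.17 and the matrix remodelling median -0.15, both now apart. With bead medians, matrix remodelling (-0.16), adipocyte (0.28) and oxidative stress and metallothionein (0.24) stood apart, and the SD between probes was 0.38; the cause was not tested for these lists. The authors' values gave 115 genes at least 2-fold higher, 71 of them among the 74, and 104 lower, 93 of them among the 102. Of the 82 other named genes, 18 moved beyond the 95% interval of their bead SE without background correction, 3 with the mean of probes (VCAM1, TPD52L1, SKP2), 1 with an offset of 50 (PALM) and 1 with bead medians (RPL29). Of the 12 highest and 12 lowest genes, 3 and 3 were less than 2-fold from equal without background correction, 1 and 1 with the mean of probes (GRIPAP1, SKP2) and 1 of the highest with bead medians (GRIPAP1). PALM and SCML1, at 1.29 and -1.06, left the third and second place without background correction. Requiring detection on both arrays left the counts as they were by construction. CCN1, the 1 detected member of the CCN family list, ranged from 0.09 with median scaling to 0.35 with bead medians. No paired analysis was possible because each group has 1 array. Signal over background limits the dim genes most. Among the 2500 dimmest genes detected on both arrays 41 were at least 2-fold higher and 42 lower, and among the 2500 brightest 7 and 20.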

Other observations

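Gene families defined by a shared symbol prefix were compared as an added test, with its prediction written before its values were seen; the count over families apart from the lists was chosen only after the result was seen. Such prefixes can hold unlike genes, as MCM does with MCM3AP and RPS with the kinase gene RPS6KA2. Of 102 prefixes with at least 8 members detected on both arrays, 12 lay outside the central 95% of brightness-matched random lists, against 5.1 by chance, where over 2 times chance had been set as the mark. Of the 91 that share no gene with a list that stood apart, 8 did so against 4.55, which is below that mark. Whether families differ together beyond random genes of the same brightness therefore stays open.

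Lower on the CTGF shRNA array were the prefixes RPL (median -0.21, 41 of 49 below 0), RPS (-0.14), MCM (-0.43) and KIF (-0.27), which share members with the ribosomal and cell cycle lists, and CEP, which holds many centrosomal proteins (-0.26, 15 of 19 below 0). Higher were GOLGA, the golgins of the Golgi apparatus (0.45, 8 of 8 above 0), RAB, mainly small GTPases of vesicle traffic (0.21, 32 of 43), VPS, genes of vacuolar protein sorting (0.24, 20 of 27), STX (0.35), SNX (0.28), PPP (0.20) and ZNF (0.14, 89 of 132). Other prefixes of membrane traffic did not stand apart, with medians of -0.19 for TMED, -0.01 for SEC, 0.08 for CHMP, 0.11 for TRAPPC and 0.22 for TBC, named after their values were seen. Under the 8 alternatives the 12 prefixes stayed outside the central 95%, except KIF and STX, which did so in 6.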
